A study of Mus musculus with 4 samples.

How the data were processed

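The series holds RNA-seq of mouse colonic mucosa, 2 WT and 2 Itch KO libraries, from total RNA with standard Illumina library preparation, per the labels' protocols. The labels give all 4 samples the state of inflammation, while the protocol calls only the knockout mucosa inflamed. Samples were grouped by genotype and title. The authors deposited raw counts per gene, 1 file per library, and the submitters' processing notes name CASAVA 1.8.2, TopHat2, SAMtools 0.1.19 and HTSeq 0.6.1 with the builds mm10 and GRCm38. The strand setting and any removal of duplicate reads are not given in the sources used here, so reads of overlapping or antisense genes could not be told apart.

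The deposited count file of WT replicate 1 lists 19308 genes with symbols and no summary lines, and the other 3 list 39179 genes and 5 HTSeq summary lines each. How the shorter list was chosen is not stated. Tests used the 19308 genes listed in all 4 files, which hold 97.3% to 97.7% of the counts of the full files. Reads outside any gene made up 23% of the total in WT replicate 2 and 18.2% and 18.3% in Itch KO replicates 1 and 2, and ambiguous reads 2.67% to 3.03%. These lines entered neither library sizes nor tests. Of the 19308 identifiers 19106 had a name and a position in GENCODE M21 (GRCm38), and exonic length is the union of annotated exons.

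Counts were compressed at the upper end. No gene held more than 9389 counts and the 10 highest genes held at most 0.633% of a library. Among the 1000 genes with the most reads per base, count and exonic length had a rank correlation of 0.949 across genes, which are not independent replicates. WT replicate 2 had 1.26 times the counts of WT replicate 1, but the median ratio of counts was 1.18 in the densest decile of genes and 1.55 in the sparsest. Given these count ratios, fold changes of highly expressed genes may be understated. The interquartile range of log2 fold changes was 0.31 in the densest decile against 1.58 in the sparsest. Their median read densities were 418 and 6.04 per kb, and counting noise also widens the range in sparse genes. That range therefore does not tell compression from noise.

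CPM values were computed with TMM factors. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with filterByExpr at a minimum count of 10, robust empirical Bayes, group as the only term and Benjamini-Hochberg adjustment at 0.05, two-sided. The biological coefficient of variation was 34.8%, with 2 residual degrees of freedom. Gene lists were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, for the 35 of 37 lists with at least 4 tested members. The 37 lists, 17 on the question of the series and 20 on other cell types, tissues, position and handling, were fixed before the data were examined, as were the tests and the rule for named genes. Camera is a competitive test that sets a list against the other genes. With a correlation estimated from the data, its test has only the 2 residual degrees of freedom. Few of the 35 lists could then pass, so a call lost there does not show that a list was unchanged. DESeq2 1.42.0 and limma voom were alternatives.

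The rule for named genes took Itch, then the 8 genes with the largest log2 fold change in each direction among called genes with a mean of at least 5 CPM whose groups do not overlap, leaving out immunoglobulin and T cell receptor segments, sex-linked genes and predicted genes. From each main list it took up to 3 called members, or the member with the highest mean level where none was called, and from each context list the member with the smallest adjusted p. It also took genes that belong to the question of the series, among them Il17a, Il17f, Il22, Il6, Tnf, Ifng and Junb. It gave 46 genes, none of them as a called gene, and some of them are not reported here. All other genes named were chosen after their values were seen. A fold against 0 counts was computed against a floor of 3 counts over the group, a limit that covers counting error only, and 3 counts correspond to 0.244 to 0.369 CPM in 1 library.

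Scripts were tested on simulated counts for 16956 genes with 200 changed genes. At the estimated dispersions edgeR called 4 of 64 genes with a 2-fold change, 38 of 66 with a 4-fold change and 49 of 65 with an 8-fold change. Camera gave a p below 0.05 for 2.4% of 500 unchanged lists of 20 genes. Simulated genes were drawn independently of each other from the fitted model. The 2.4% therefore does not cover lists whose members are correlated, and edgeR's calls there may overstate its power in the real libraries. Alternatives were another normalization (RLE, upper quartile), other filters (none, a mean of at least 5 CPM), DESeq2, limma voom, glmTreat, robust=FALSE, a replicate block, each library left out, and for lists an estimated correlation and fry. Added after seeing the data were edgeR's legacy=FALSE estimator, a fit with each library's trend on exon length removed, a fit of all genes of the 3 full files, and variants of DESeq2. The WT replicates were not the same library deposited again, since their counts differed by far more than sampling noise (chi-square per degree of freedom 33.4, and 25.6 for the knockout replicates).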

Results

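Transcript levels were measured by RNA sequencing of total RNA from colonic mucosa of C57BL/6 mice that were either wild-type (WT) or lacked Itch, the gene of the HECT-type E3 ubiquitin ligase ITCH. Each group held 2 libraries, and the mucosa of the knockout mice was described as inflamed. The comparison asks how the transcript profile of inflamed Itch knockout (KO) mucosa differs from that of WT mucosa. Over the 19308 genes listed for every library, total counts were 9674531 in WT replicate 1, 12199709 in WT replicate 2, 8181193 in Itch KO replicate 1 and 9463759 in Itch KO replicate 2. Nothing in the labels says that the replicates came from separate animals, so p-values measure only the spread between these libraries.

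Itch itself (ENSMUSG00000027598, GRCm38 chromosome 2, 155133509 to 155226855, plus strand, protein-coding) was low in both knockout libraries. It stood at 204 and 183 CPM (counts scaled by library size) in the WT libraries and at 11.9 and 13.4 CPM in the knockout libraries, a mean of 193 ± 14.3 against 12.7 ± 1.07 (SD, n = 2 each). The log2 fold change was -3.93 with a standard error of 0.15. Its edgeR quasi-likelihood p was 5.44e-06 and its Benjamini-Hochberg adjusted p 0.0922, while DESeq2 gave an adjusted p of 9.62e-57. The 97 and 130 counts that remained in the knockout libraries were assigned to the gene as a whole and do not show which exons were transcribed.

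The planned per-gene test called no gene: of 16956 genes tested with edgeR, 0 were higher and 0 lower at an adjusted p below 0.05, and Itch had the smallest adjusted p. At an unadjusted p below 0.05 there were 3343 genes, 1729 higher and 1614 lower in knockout mucosa, where 848 would be expected with no effect. limma voom called 0 genes in either direction. DESeq2, an alternative, called 919 genes higher and 818 lower, and the decision to give its calls as results of their own was made after the edgeR count was seen. Without Itch KO replicate 2 its counts were 170 higher and 286 lower, without Itch KO replicate 1 679 and 560, without WT replicate 1 824 and 366, and without WT replicate 2 596 and 314. On simulated data with the dispersions of these libraries, edgeR called 38 of 66 genes with a 4-fold change and 49 of 65 with an 8-fold change, with 21 unchanged genes called. DESeq2 called 46 of 67 and 59 of 66 there, with 93 unchanged genes called. The simulated counts held only the spread of the fitted model. Since edgeR called no gene in the real libraries, they may overstate its power. In the values below, single genes are therefore given by level and log2 fold change, and directions are stated for gene lists that were fixed before the data were examined. List members that passed edgeR's test adjusted over their list alone are also given. That adjustment does not span the lists, and no such gene passed over all genes.

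**Figure D1:**
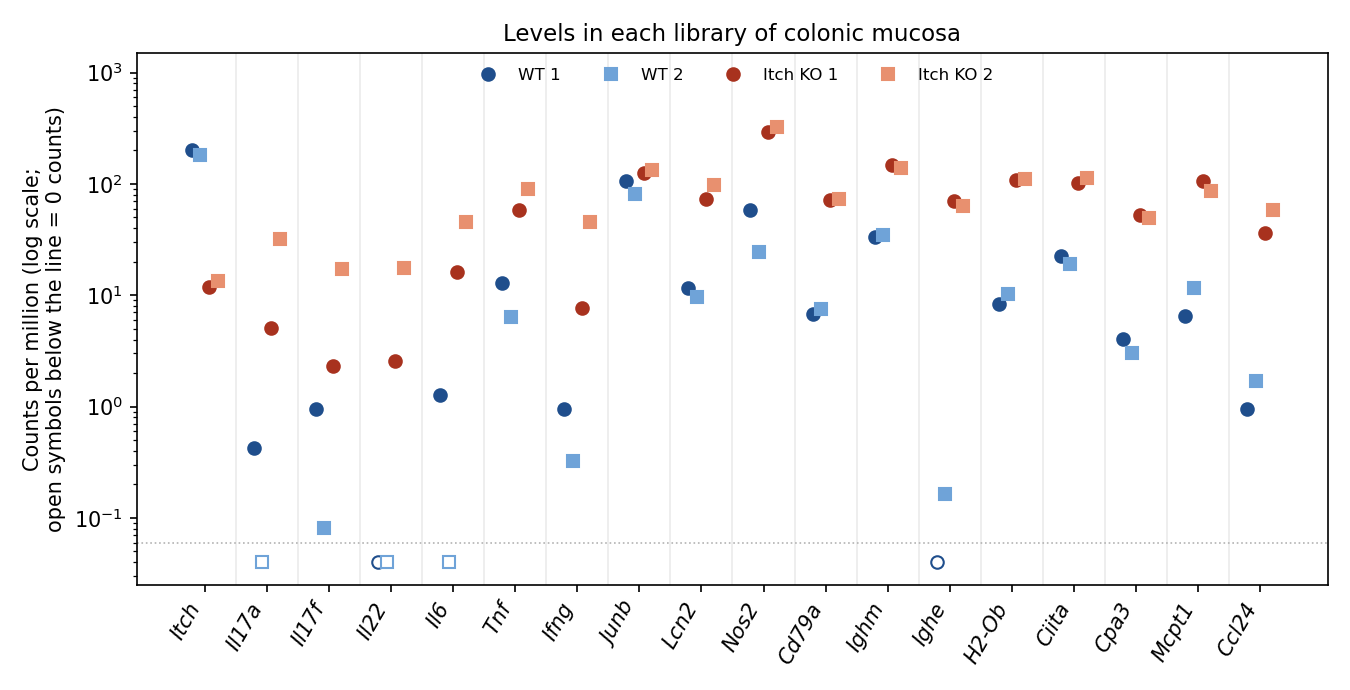
CPM (log axis) of 18 genes in each of the 4 libraries, with circles for replicate 1 and squares for replicate 2 and with open symbols for 0 counts. Itch lay at 11.9 and 13.4 CPM in the knockout libraries against 204 and 183 in WT, and Cd79a at 72.4 and 73 against 6.83 and 7.5.

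Genes of the Th17 axis, the cells and cytokines of interleukin-17 immunity, rose as a list in knockout mucosa, with a median log2 fold change of 2.58 over 18 tested members. Il17a, the founding cytokine of the family, was at 0.427 and 0 CPM in WT and at 5.04 and 31.7 CPM in knockout libraries, and Il17f was at 0.96 and 0.0815 against 2.33 and 17.4. Il22 had 0 counts in both WT libraries and 21 and 170 in the knockout libraries, at least 77.3-fold higher when set against a floor of 3 counts over the WT group. The receptor subunit gene Il17rc overlapped between groups, at 129 and 118 against 155 and 110 CPM. The list was called by camera with a preset correlation (adjusted p = 1.52e-05), but not with one estimated from the data (adjusted p = 0.555 with an estimated correlation). Here and below, the estimated setting leaves 2 degrees of freedom, with which few lists could pass. Adjusted over the list alone, 10 of the 18 members passed edgeR's test, all higher, among them Irf4, Ccr6, Batf, Il22, Il17a and Il6, and over all genes none did. Members such as Il17a, Il17f and Il22 were several times higher in Itch KO replicate 2 than in replicate 1.

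Genes that epithelia induce in response to interleukin-17 and interleukin-22 also rose as a list (20 members, median 1.05, camera adjusted p = 9.09e-06). That call was lost with an estimated correlation (adjusted p = 0.555). Lcn2, which encodes an iron-sequestering antimicrobial protein, averaged 10.6 ± 1.35 CPM in WT and 85.6 ± 16.6 in knockout mucosa, Nos2 41.2 ± 23.8 against 309 ± 21.3, and Mmp3 9.24 ± 7.3 against 128 ± 34.3 (SD, n = 2 each). These 3 members passed edgeR's test adjusted over the list alone, and Pigr, the transporter of polymeric immunoglobulin, overlapped at 400 and 321 against 438 and 317 CPM. Inflammatory cytokines and chemokines rose together (19 members, median 2.90, camera adjusted p = 2.2e-08, adjusted p = 0.555 with an estimated correlation), and 12 of them passed edgeR's test adjusted over the list alone. Tnf went from 12.9 and 6.36 to 58.5 and 89.9 CPM, Ccl4 from 0.854 and 1.14 to 18.7 and 46.1, and Il6 from 1.28 and 0 to 16.1 and 45. Il1rn, an antagonist of interleukin-1, was at 137 and 55.4 against 153 and 192 CPM.

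B cell and plasma cell genes showed the smallest camera p of all lists, with a median log2 fold change of 3.07 over 17 members. Every member was higher in both knockout libraries than in both WT libraries. A separation in that direction held for 5090 of the 16956 tested genes, and chance gives one in either direction for 33.3% of genes. Cd79a and Cd79b, which encode the signalling chains of the B cell receptor, were at 6.52 to 8.43 CPM in WT and 72.4 to 80.6 CPM in knockout libraries. Ighm, the IgM heavy chain, averaged 33.9 ± 1.09 against 143 ± 6.72 CPM, and the plasma cell and epithelial gene Sdc1 180 ± 11.1 against 199 ± 2.34 (SD, n = 2 each). Camera gave an adjusted p of 1.63e-11, or 0.473 with an estimated correlation, and fry, which tests whether the members move one way, an adjusted p of 0.006. Of the 17 members, 14 passed edgeR's test adjusted over the list alone. Counts of immunoglobulin genes may be split among near-identical segments, so the single segments are not reported.

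Genes of MHC class II antigen presentation rose as well (13 members, median 1.70, camera adjusted p = 5.98e-09, adjusted p = 0.555 with an estimated correlation). Of these 12 passed edgeR's test adjusted over the list alone. H2-Ob averaged 9.31 ± 1.24 CPM in WT and 109 ± 1.89 in knockout mucosa, Ciita, the master activator of these genes, 20.8 ± 2.43 against 107 ± 7.96, and Cd74 88.5 ± 16.4 against 147 ± 9.35 (SD, n = 2 each). T cell genes rose with a median of 1.57 over 17 members (camera adjusted p = 5.98e-09, adjusted p = 0.555 with an estimated correlation). Cd2 was at 5.23 and 5.46 CPM in WT against 29.9 and 39.4, and Lck, the kinase of T cell receptor signalling, at 13.7 and 30 against 48.7 and 65.1, with 8 members past edgeR's test adjusted over the list alone. Regulatory T cell genes rose on balance (13 members, median 1.85, camera adjusted p = 0.00021, adjusted p = 0.555 with an estimated correlation). Adjusted over the list alone, 8 of them were higher, including Ctla4, Icos, Foxp3 and Tgfb1, and Ikzf2 was lower, at 76.3 ± 4.51 CPM in WT against 29.9 ± 9.85 in knockout mucosa (SD, n = 2 each).

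Innate cell genes pointed the same way. Neutrophil genes had the largest median of the called lists, 3.65 over 17 members (camera adjusted p = 1.27e-07, adjusted p = 0.555 with an estimated correlation), and 9 passed edgeR's test adjusted over the list alone. The mean log2 CPM of the neutrophil list was 3.26 and 1.495 in the WT libraries against 4.94 and 5.89. Ngp was at 1.17 and 0.326 CPM in WT and 29.6 and 70.4 in knockout libraries, while Cd177, was at 189 and 131 against 256 and 200. Monocyte and macrophage genes had a median of 0.81 over 16 members (camera adjusted p = 1.52e-05, adjusted p = 0.565 with an estimated correlation), with 9 past edgeR's test adjusted over the list alone. Csf1r, the receptor for the macrophage growth factor, went from 89.9 and 61.2 to 155 and 208 CPM. Interferon-induced genes had a median of 0.84 over 27 members (camera adjusted p = 5.33e-08, adjusted p = 0.555 with an estimated correlation), and 17 passed adjusted over the list alone in edgeR. Cxcl9, a chemokine induced by interferon, averaged 10.9 ± 8.08 against 142 ± 49.2 CPM (SD, n = 2 each), and Ifng, the type II interferon, was at 0.96 and 0.326 against 7.62 and 45.5.

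Genes of the type 2 response rose (17 members, median 1.34, camera adjusted p = 1.46e-05, adjusted p = 0.555 with an estimated correlation), with 8 members past edgeR's test adjusted over the list alone. Il4ra, the receptor chain shared by interleukin-4 and interleukin-13, was at 109 and 121 CPM in WT and 250 and 288 in knockout libraries. Junb, a transcription factor that ITCH is known to target, was at 105 and 80.9 against 125 and 133 CPM (log2 fold change 0.47, SE 0.17, edgeR adjusted p = 0.247). Mast cell and eosinophil genes had a median of 3.08 over 15 members (camera adjusted p = 1.27e-07, adjusted p = 0.473 with an estimated correlation, fry adjusted p = 0.0202). Cpa3, a mast cell protease gene, averaged 3.53 ± 0.735 CPM in WT and 51.2 ± 1.91 in knockout mucosa (SD, n = 2 each), and 9 members passed edgeR's test adjusted over the list alone. Genes of natural killer and cytotoxic cells (median 1.64, camera adjusted p = 0.000963, adjusted p = 0.565 with an estimated correlation) and of dendritic cells (median 0.93, camera adjusted p = 0.00265, adjusted p = 0.576 with an estimated correlation) were called higher too, with Gzma at 5.87 and 4.16 against 35.9 and 42.4 CPM and Ccr7 at 3.63 and 3.91 against 22.7 and 52.2.

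**Figure D2:**
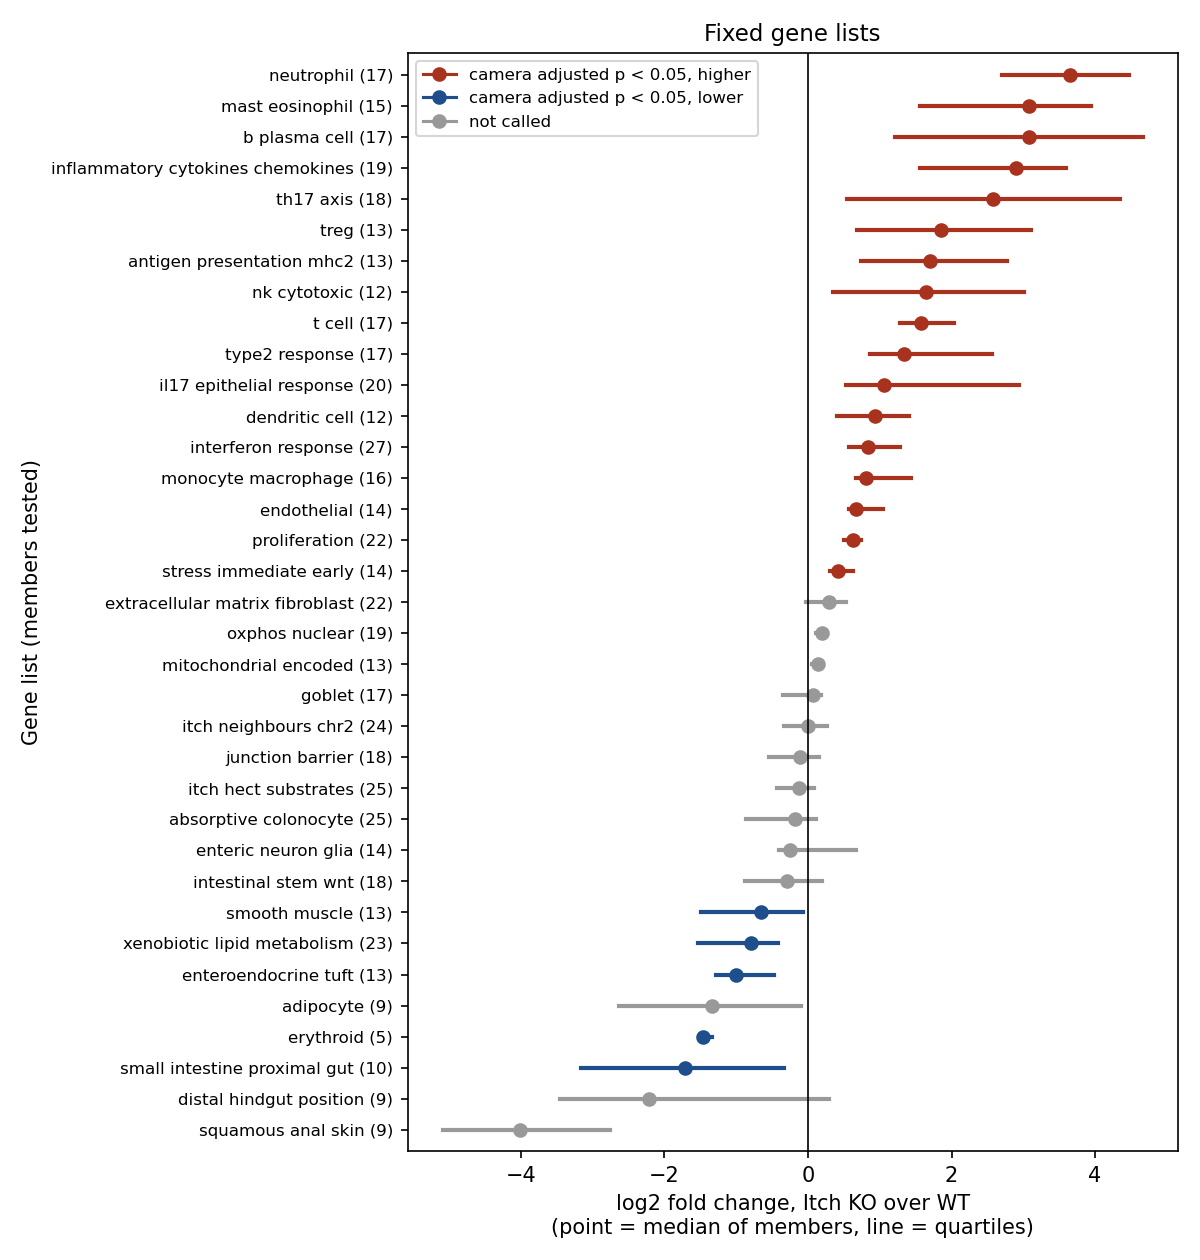
Median log2 fold change (point) and quartiles (line) of the tested members of 35 fixed gene lists, knockout over WT, with the number of members in brackets and colours for camera's call at a preset correlation. Neutrophil genes had a median of 3.65 and small intestine genes one of -1.71. None of the 22 calls held with an estimated correlation, a setting with 2 degrees of freedom in which few lists could pass.

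Cell division genes rose by a smaller amount (22 members, median 0.63, camera adjusted p = 4.71e-07, adjusted p = 0.565 with an estimated correlation). Of these genes 12 passed edgeR's test adjusted over the list alone, including Mcm3 and Aurka, whereas Mki67 overlapped at 292 and 195 against 275 and 196 CPM. Stem cell and Wnt target genes were not called as a list (18 members, median -0.29, camera adjusted p = 0.0627). Lgr5, a marker of crypt base stem cells, was nevertheless at 35.5 and 68.8 CPM in WT and 8.72 and 6.71 in knockout libraries, and Lgr5, Axin2 and Znrf3 were lower by edgeR adjusted over the list alone, while Ephb2 overlapped at 188 and 210 against 205 and 156 CPM.

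Epithelial genes of xenobiotic and lipid metabolism fell as a list (23 members, median -0.79, camera adjusted p = 6.01e-05, adjusted p = 0.555 with an estimated correlation), with all 23 log2 fold changes negative and no member past edgeR's test adjusted over the list alone. The mean of the list differed between the WT libraries, at a log2 CPM of 5.77 in replicate 1 and 6.52 in replicate 2, against 5.30 and 4.999 in the knockout libraries, and without WT replicate 2 its adjusted p was 0.00435. Cyp2s1, a cytochrome P450, was at 191 and 140 CPM in WT and 72.4 and 47.4 in knockout libraries. Absorptive colonocyte genes (25 members, median -0.18, camera adjusted p = 0.201) and junction genes (18 members, median -0.11, adjusted p = 0.256) were not called, but both were called lower without Itch KO replicate 1 (adjusted p = 0.0106 and 0.00716). Slc26a2, a sulfate transporter, was at 511 and 450 against 323 and 205 CPM, and Mylk, the myosin light chain kinase, at 379 and 281 against 161 and 204. Goblet cell genes were not called (17 members, camera adjusted p = 0.636), and their median of 0.08 and mean of -0.20 differed in sign, with a call as lower only without Itch KO replicate 1 (adjusted p = 0.00837). Fcgbp overlapped at 621 and 521 against 734 and 470 CPM. Enteroendocrine and tuft cell genes fell (13 members, median -0.998, camera adjusted p = 0.0132, adjusted p = 0.565 with an estimated correlation), with Chga, a hormone granule gene, at 82.9 and 126 against 46.4 and 39.7 CPM. Chga and Neurod1 were lower and Tac1 higher by edgeR adjusted over the list alone. The mean log2 CPM of that list was 4.52 and 5.53 in the WT libraries against 4.14 and 3.91, and its call ended without WT replicate 2 (adjusted p = 0.0586) and without Itch KO replicate 2 (adjusted p = 0.0845).

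Fibroblast and matrix genes (22 members, median 0.29, camera adjusted p = 0.134) were not called, with Col3a1 at 438 and 272 against 374 and 469 CPM, but were called higher without WT replicate 1 (adjusted p = 0.00164), without Itch KO replicate 1 (adjusted p = 0.00673) and with the trend on exon length removed (adjusted p = 0.0376). The list of ITCH, related ligases and ITCH substrates was not called either (25 members, median -0.12, adjusted p = 0.201), except as lower without WT replicate 2 (adjusted p = 0.0277). Besides Itch, Wwp1, a related HECT ligase, and Notch1 were lower and Ripk2 higher by edgeR adjusted over the list alone, and Nedd4 overlapped at 373 and 293 against 293 and 285 CPM. Genes near Itch on chromosome 2 had a median of 0.01 over 24 members (adjusted p = 0.972). Nuclear oxidative phosphorylation genes (median 0.19, adjusted p = 0.0755), mitochondrially encoded genes (median 0.14, adjusted p = 0.401) and enteric neuron and glia genes (median -0.26, mean -0.02, adjusted p = 0.868, with an upward direction in camera) did not pass, although the first were called higher without Itch KO replicate 2 (adjusted p = 0.00126) and the last without Itch KO replicate 1 (adjusted p = 0.0485). Cycs was at 57.6 and 65.4 against 85.8 and 70.5 CPM, mt-Atp6 at 65.9 and 58.2 against 76.9 and 65.1, and Vip, a neuropeptide gene, at 33.1 and 43.1 against 74 and 95.6. Mitochondrially encoded genes held at most 0.15% of the counts of a library. Their counts may be compressed, so their levels are uncertain and the missing call does not show equal levels.

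Markers of other tissues and gut positions differed between libraries of the same group. Squamous epithelium genes were high in WT replicate 1 alone, with Krt5 at 138 CPM there against 0.244 in WT replicate 2 and 0.86 and 3.1 in the knockout libraries, and Krt10 at 91 against 10.5, 8.72 and 7.95. The list was not called (9 members, median -4.01, camera adjusted p = 0.224), but it was called higher without WT replicate 1 (adjusted p = 0.000352) and lower without WT replicate 2 (adjusted p = 5.63e-17). Posterior hindgut genes were not called (9 members, median -2.22, adjusted p = 0.0998) except as lower without WT replicate 2 (adjusted p = 5e-05), with Hoxd13 at 147 and 0.978 CPM in WT against 13.5 and 21.4, and Hoxc10 at 2.13 and 2.12 against 0 in both knockout libraries. Hoxc10 and Hoxd10 were lower by edgeR adjusted over the list alone. Small intestine genes were called lower (10 members, median -1.71, camera adjusted p = 0.0136, adjusted p = 0.555 with an estimated correlation), with Slc10a2, the ileal bile acid transporter, at 27.3 and 95.5 against 7.13 and 3.31 CPM. Smooth muscle genes were called lower (13 members, median -0.66, camera adjusted p = 0.0154, adjusted p = 0.741 with an estimated correlation), with Myh11 at 590 and 393 against 199 and 271 CPM. That call ended without WT replicate 1 (adjusted p = 0.486) and without Itch KO replicate 1 (adjusted p = 0.082).

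Red blood cell genes were called lower (5 members, median -1.47, camera adjusted p = 0.00234, adjusted p = 0.565 with an estimated correlation), with Alas2 at 2.88 and 4.16 against 0.491 and 0.62 CPM. Endothelial genes were called higher (14 members, median 0.66, adjusted p = 0.0143, adjusted p = 0.741 with an estimated correlation), with Icam1, a leukocyte adhesion molecule, at 36.2 and 19.6 against 57.6 and 98 CPM, but not without WT replicate 2 (adjusted p = 0.17) or without Itch KO replicate 2 (adjusted p = 0.36). Immediate early and heat shock genes were called higher (14 members, median 0.42, adjusted p = 0.0205, adjusted p = 0.737 with an estimated correlation), with Hsp90aa1 at 108 and 104 against 156 and 153 CPM. That call ended without WT replicate 2 (adjusted p = 0.443), without Itch KO replicate 2 (adjusted p = 0.128) and with the trend on exon length removed (adjusted p = 0.0692). Adipocyte genes were not called (9 members, median -1.34, adjusted p = 0.13), but were called lower without WT replicate 1 (adjusted p = 0.00116) and without Itch KO replicate 2 (adjusted p = 0.00956), with Plin4 at 81.9 and 90.5 against 6.14 and 21.5 CPM. Of the pancreatic acinar genes only 3 were tested, too few for a list test, and Ctrb1 was at 83.9 CPM in Itch KO replicate 2 against 0.747 to 1.22 in the other libraries. Of the sex-linked genes only Xist was tested, at 654 and 555 against 461 and 349 CPM.

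**Figure D3:**
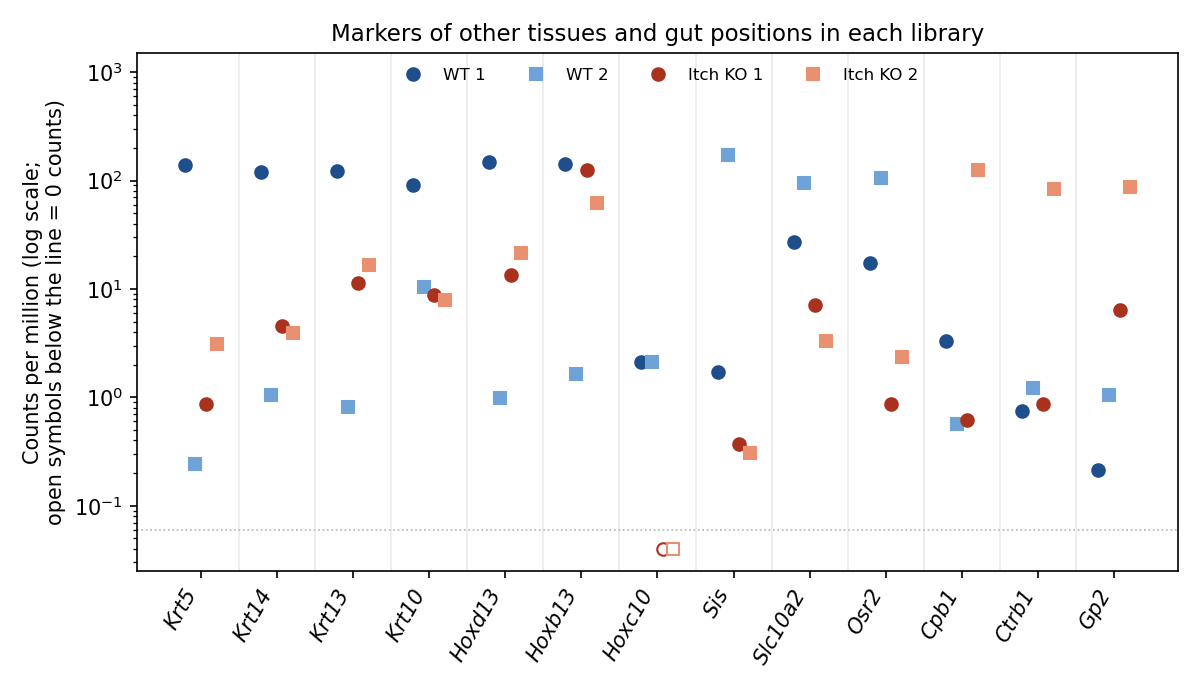
CPM (log axis) of 13 markers of squamous epithelium, gut position, small intestine and pancreas in each library, with circles for replicate 1, squares for replicate 2 and open symbols for 0 counts. Krt5 stood at 138 CPM in WT replicate 1 and at 0.244 in WT replicate 2, and Ctrb1 at 83.9 in Itch KO replicate 2.

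The groups lay further apart than the replicates over all genes. The first principal component held 61.2% of the variance and separated knockout from WT libraries, and the second, with 23.4%, separated mainly the WT libraries from each other. Of the tested genes 56% had both knockout libraries on the same side of both WT libraries, where chance gives 33.3%. Log2 fold changes depended on gene length: the median was 0.27 in the quintile of genes with the shortest exonic length and -0.28 in the quintile with the longest. Members of the immune lists had a median exonic length of 2516 bases against 4025 for all tested genes. Without them the difference between the longest and the shortest quintile was -0.54, against -0.55 with them. They were only 211 of the 16805 genes with a length, too few to shift these medians much whatever the cause of the trend. With the length trend removed, an alternative added after it was seen, the immediate early and heat shock list lost its call, the fibroblast and matrix list gained one, and the other calls held.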

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

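All explanations of the WT difference were tested only after it was seen, and the genes of the 3 full files were compared after the data were seen. The test of count ratios by read density was also chosen after its result was seen, while both tests of the length trend were fixed beforehand.

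Among the 19871 genes listed for 3 libraries but not for WT replicate 1, which enter no comparison of all 4 libraries, 1071 reached 5 CPM in some library. Of these, 5 had at least 5 CPM in both knockout libraries and were over 4 times higher there than in WT replicate 2, and 8 had at least 5 CPM in WT replicate 2 and were over 4 times lower in both knockout libraries. With a single WT library there is no replicate check. H2-Q5, an MHC class I gene with near-identical copies, was at 51.2 and 67.2 CPM against 11.2, and the others were C920009B18Rik, Gm15922, Gm11427 and Gm15925.

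The WT libraries differed from each other in squamous keratins, HOX genes and small intestine genes. Exchange of a WT with a knockout library is argued against by Itch, whose lowest WT level was 13.7 times its highest knockout level. Squamous tissue from the anal margin stays open. Of the 9 tested members of the squamous list, none of them in another list, 100% were over 4 times higher in WT replicate 1 than in each other library. Krt5 was at 138 CPM there and Krt6a at 134. Since 6 of the 9 are keratins, the genes that prompted the test, this share does not decide. The 3 others, Col17a1, Dsg3 and Dsc3, were at 103, 54.1 and 36.4 CPM there against at most 1.55, 1.45 and 3.61 elsewhere. Krt1, Krt4, Trp63, Lor and Sprr3 had too few counts to test. Squamous transcripts were thus high in WT replicate 1 beyond the keratins, but which tissue they came from was not tested. A different position along the gut stays open too. Over 29 HOX genes the rank correlation of paralog number with the difference between the WT libraries was 0.637. Its permutation p was 0.00031 (two-sided, across genes that are not independent). HOX genes were among those that prompted this test, so it does not decide either. Individual variation was not tested, and lists tied to position, such as small intestine genes, rest on WT libraries that differ in this way.

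Log2 fold changes fell with exon length, with a difference of -0.55 between the longest and the shortest quintile of genes (95% bootstrap interval -0.57 to -0.52), against 0.03 between the WT libraries and -0.01 between the knockout libraries. The intervals in this paragraph come from resampling genes as if independent, so they do not cover the spread between libraries. Unequal depth is argued against as the cause, since the difference was -0.47 (-0.50 to -0.45) between Itch KO replicate 2 and WT replicate 1, whose totals nearly match. Removal of duplicate reads could compress densely covered genes: the median count ratio between the WT libraries was 0.222 lower in the densest decile than among genes below the median density. It is argued against as the whole cause of the length trend, which was -0.36 (-0.45 to -0.30) among genes below the median read density. RNA integrity, library preparation and the knockout itself stay open, as none was tested. Whether RNA integrity or library preparation differed between the groups is not given in the sources used here.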

How the results depend on the processing

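The settings with the length trend removed, legacy=FALSE, the 3 full files and the variants of DESeq2 were chosen after seeing the data. The counts of 0 genes higher and 0 lower held in every edgeR and limma voom setting, leaving out each library included, with smallest adjusted p from 0.0629 to 0.421. DESeq2 called 919 higher and 818 lower, and Itch passed with it alone (log2 fold change -3.95, against -4.01 to -3.69 elsewhere). Leaving out each library moved DESeq2's counts to 170 to 824 higher and 286 to 560 lower, and 164 higher and 68 lower genes kept their call throughout. With the replicate block, whose numbers are not stated to pair mice (correlation of same-numbered deviations 0.048), edgeR called 0 and 0, DESeq2 665 and 427, and camera 24 lists, adding adipocyte genes as lower (adjusted p = 0.0115) and nuclear oxidative phosphorylation genes as higher (0.047). Camera's 22 lists became 0 with an estimated correlation, 2 with fry and 21 to 27 without each library. Squamous genes had an adjusted p of 5.63e-17 to 0.206 over the libraries left out, and turned upward without WT replicate 1 (0.000352). With the length trend removed, log2 fold changes reversed for Ephb2 (0.21), Mki67 (0.21), Nedd4 (0.0907), Il17rc (-0.0199) and mt-Atp6 (-0.073), none of them called. Arntl was at -0.00593 with RLE factors, and Hoxd13 at 0.12 with the block and 0.90 with voom. Leaving out single libraries moved across 0 the log2 fold changes of Hoxd13 (-3.07 to 4.16), Krt5 (-6.30 to 2.99), Krt6a (-6.45 to 3.16), Cpb1 (-1.62 to 6.78), Ctrb1 (-0.19 to 6.38), Col3a1 (-0.0567 to 0.66), Ephb2 (-0.35 to 0.0519), Fcgbp (-0.28 to 0.37), Il17rc (-0.17 to 0.34), Mki67 (-0.32 to 0.29), Nedd4 (-0.37 to 0.00131), Npas2 (-0.53 to 0.29), Arntl (-0.16 to 0.19) and Pigr (-0.18 to 0.29). The cause of these changes was not tested. Depth limits genes near the floor, where 3 counts were worth 0.244 to 0.369 CPM in a library.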

Other observations

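The single genes in this part, except the nonagouti gene, were chosen after their values were seen, and the test of the nonagouti gene was chosen after its result was in view, while the test of clock genes was fixed after Dbp, Per3 and Hlf had been seen but before the genes it measures were looked at.

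Heavy chain classes differed in how far their levels lay apart. Ighe, the IgE heavy chain, had 0 and 2 counts in the WT libraries and 570 and 616 in the knockout libraries, a ratio of 720 with a counting interval of 199 to 5954, and averaged 66.8 ± 4.54 CPM in the latter (SD, n = 2). Ighg1 averaged 4.13 ± 4.18 CPM in WT and 102 ± 5.34 in knockout mucosa, whereas Igha, the class that dominates in the gut, averaged 75.3 ± 14.4 against 122 ± 11.5. Counts of densely covered genes were compressed, so fold changes may be understated to unlike degrees across the classes. Mast cell proteases had similar levels in both knockout libraries, with Mcpt1 at 107 and 86 CPM against 6.51 and 11.6 in WT, Mcpt2 at 78.6 and 63.6 against 3.31 and 5.38, and Cma2 at 63 and 43 against 0.213 and 0.163. These proteases and Ighg1 have close paralogs, so their single levels are uncertain. Ccl24, a chemokine that attracts eosinophils, was at 36.1 and 57.7 CPM against 0.96 and 1.71. None of these genes passed edgeR's test adjusted over all genes (adjusted p = 0.109 for Cma2 to 0.179 for Igha).

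Itch KO replicate 2 alone held pancreatic Cpb1 at 124 CPM, against 0.57 to 3.31 in the other libraries. Gp2 was at 86.2 CPM in Itch KO replicate 2 and 6.39 in Itch KO replicate 1, against 0.213 and 1.06 in WT replicates 1 and 2.

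Clock output genes were low in both knockout libraries, with Dbp at 18.8 and 15 CPM against 80.4 and 74.6 in WT, Per3 at 46.3 and 28.5 against 172 and 126, and Hlf at 5.16 and 12 against 56.1 and 48.3. Harvest at a different phase of the day may lower these genes, and would then raise genes of the opposite phase. The 6 same-phase genes Per1, Per2, Nr1d1, Nr1d2, Ciart and Tef had a median log2 fold change of -0.996, but the 5 opposite-phase genes Arntl, Npas2, Clock, Cry1 and Nfil3 had one of 0.02, less than a shift in phase was predicted to give. These members went both ways, with Nfil3 at 1.91 and Clock at -0.68, so the difference of 1.02 leaves phase and a lower clock output of another kind such that they cannot be told apart, and the hours of harvest are not given in the sources used here.

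The nonagouti gene (symbol a, GRCm38 chromosome 2, 154791402 to 155051012), next to Itch, had 0 counts in both WT libraries and 9 and 15 in the knockout libraries. The knockout allele could also alter this neighbouring locus. However, 34 of the 19308 genes had 0 counts in both WT libraries and at least 9 in both knockout libraries, among them Il13, Il21 and Gzmd. That number lay between those set to argue for and against a local effect. A count over all genes also does not show whether the allele alters this locus in particular. A local and a general effect therefore cannot be told apart.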
